A study of Homo sapiens and Mus musculus and blank sample with 48 samples.

How the data were processed

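Single-cell RNA libraries were made from TOV-21G, an established human ovarian clear cell carcinoma line, and from layer V pyramidal neurons in motor cortex slices of Thy1-YFP mice. RNA was taken from single cells through glass patch pipettes by LC-seq, in which β-escin perforates the membrane of a living cell, or by WC-seq, an abbreviation that the labels do not spell out. Some TOV-21G cultures received IKK-16, an inhibitor of IκB kinase, at 1 µM for 72 hours. Water libraries served as blanks. The library chemistry is not given in the labels.

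The deposited tables hold raw read counts per Ensembl gene, 1 column per library, with no normalization. Of the tools, the submitters' processing notes name bcl2fastq, FastQC, HISAT2 2.1.0 and HTSeq 0.11.2, and they list the genome builds GRCh38 and mm9. The notes tie neither build to a table, and they state no annotation or filter. The labels mention no molecular identifiers, so read counts are not independent molecules, and every interval and limit given here covers counting error only.

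Of the 58302 human gene identifiers, 58039 were matched to GENCODE release 29 for names, gene types and GRCh38 positions; 0.0678% of the human counts lay on the others. None of the 53465 mouse identifiers could be given a name, because no mouse annotation was at hand. Mouse genes are therefore given by identifier, and the planned mouse gene lists and a mouse total without mitochondrial genes were left out.

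Levels were expressed in CPM, read counts scaled to a library total of 1000000, and a group's level of a gene was the mean over cells of log2(CPM + 10). Libraries whose descriptions share a stem were averaged into 1 cell, an assumption, since the labels do not say what the ending dup means. Libraries under 10000 gene counts were left out of levels but kept for totals, shares and detection. A human gene counted as measured with at least 5 counts in at least 3 cells of the compared groups, and a mouse gene in at least 2 cells. No LC-seq neuron reached 10000 counts, so the neurons are reported without that minimum, a setting planned as an alternative.

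Each cell library was taken as RNA of 1 cell, with up to 2 libraries per cell, and the labels name no animal, donor or culture, so each group counts as 1 sample. No test was made and no p-value is given. Values are differences of group means, with the SD over cells and, for counts, exact Poisson or exact Clopper-Pearson binomial 95% intervals. A count of 0 was read as allowing up to 3 counts of the total. The description prefixes G281, TS and G216, whose meaning the labels do not give, were treated as possible batches, and values within them stand beside the pooled ones.

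For human cells 18 gene lists were fixed before the data were examined, as were the comparisons, the filters, the naming rule and the other settings to be tried. They cover mitochondrially encoded genes, nuclear-encoded respiratory chain, cytosolic ribosomal proteins, nuclear-retained RNAs, cytoskeleton, glycolysis, endoplasmic reticulum folding, immediate early and stress genes, NF-κB targets, NF-κB pathway components, cell cycle G1/S and G2/M, apoptosis, ovarian clear cell carcinoma markers, membrane transport and channels, and RNA of keratinocytes, blood and fibroblasts. Each list's median difference was placed among 10000 random lists of the same size drawn from the same level bins (10 bins, seed 20). A list inside the central 95% of those lists is described as inside the random range. The percentile describes these libraries and is not a p-value.

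Named genes were the 10 protein-coding genes with the largest difference each way under the following rule. The gene had at least 5 counts in at least 50% of the cells of the higher group. In the LC-seq and WC-seq comparison its difference also had the same sign in the G281 and the TS prefix. In the IKK-16 comparisons every treated cell lay on that side of the untreated median of its prefix. For neurons the rule required 5 counts in at least 2 cells of the higher group and no overlap between the groups. The limit to protein-coding genes could not be applied there, for want of mouse names and gene types. Other genes appear as members of a fixed list; HBB, BCL2 and single NF-κB targets were singled out after their values were seen.

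Genes detected were counted as genes with at least 5 counts after thinning each library to 100000 counts. Few libraries reached that depth, so a depth of 5000, and of 100 for neurons, and counts of genes with at least 1 count at 5000 or unthinned, were added after seeing the data. Also added then were the exclusion of libraries whose description ends in dup, a total without HBB, shares restricted to libraries of at least 10000 counts, the share of summed counts on NF-κB targets, the IKK-16 comparisons without each untreated cell, and the sums of single targets and the bounds of genes at 0 without each cell. The settings fixed beforehand were TMMwsp factors from edgeR 4.0.16, poscounts size factors from DESeq2 1.42.0, a total without mitochondrially encoded genes, pseudocounts of 1 and 100, ratios of mean CPM and of summed counts, no filter on low counts, no library minimum and a minimum of 100000, libraries counted separately and single prefixes. Cells left out in turn were the WC-seq cells in the comparison of methods, the treated cells with IKK-16, and all neurons. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

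The pipeline was tested on simulated data with known folds. Each library was drawn as Poisson counts around 1 mean profile, so the simulated cells lacked the variation between real cells. Recovery therefore describes the calculation under counting error only and does not carry over to single genes of these cells. In the LC-seq and WC-seq layout, 50 genes simulated at fold 8 had a median recovered log2 difference of 3.24, and 50 of 50 had the simulated sign. At fold 2 the median was 0.79 and 46 of 50 had the sign. At fold 0.125, a log2 difference of -3, the median was -2.16 and 50 of 50 had the sign. With IKK-16 in LC-seq the median at fold 8 was 2.83 with 48 of 48 signs, and in WC-seq it was 2.80 with 50 of 50. Unaltered genes had a median of -0.19 in both IKK-16 layouts. The neuron layout held 21 genes, and 2 of 2 genes at fold 8 had the sign with a median of 2.23. Its 11 unaltered genes had a median of -3.18, a bias toward the deeper WC-seq cells.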

Results

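The data comprised 42 human and 6 mouse libraries. Untreated TOV-21G cells gave 21 LC-seq libraries from 17 cells and 10 WC-seq libraries from 8 cells. IKK-16-treated cells gave 4 LC-seq libraries from 3 cells and 3 WC-seq libraries from 2 cells. These numbers of cells assume that libraries whose descriptions share a stem come from 1 cell, which the labels do not state. Water gave 4 libraries, and neurons gave 3 libraries by each method. The series compares RNA profiles of living cells in culture and in brain slices between both collection methods. The median total of gene counts was 13770 in LC-seq (range 708 to 595009) and 17871 in WC-seq (6522 to 684968). Treated libraries had medians of 6811 in LC-seq (1941 to 243533) and 17821 in WC-seq (6585 to 19365). Water held 105 to 900 counts. Neurons held 131 to 2938 counts in LC-seq and 7993 to 19933 in WC-seq.

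**Figure D1:**
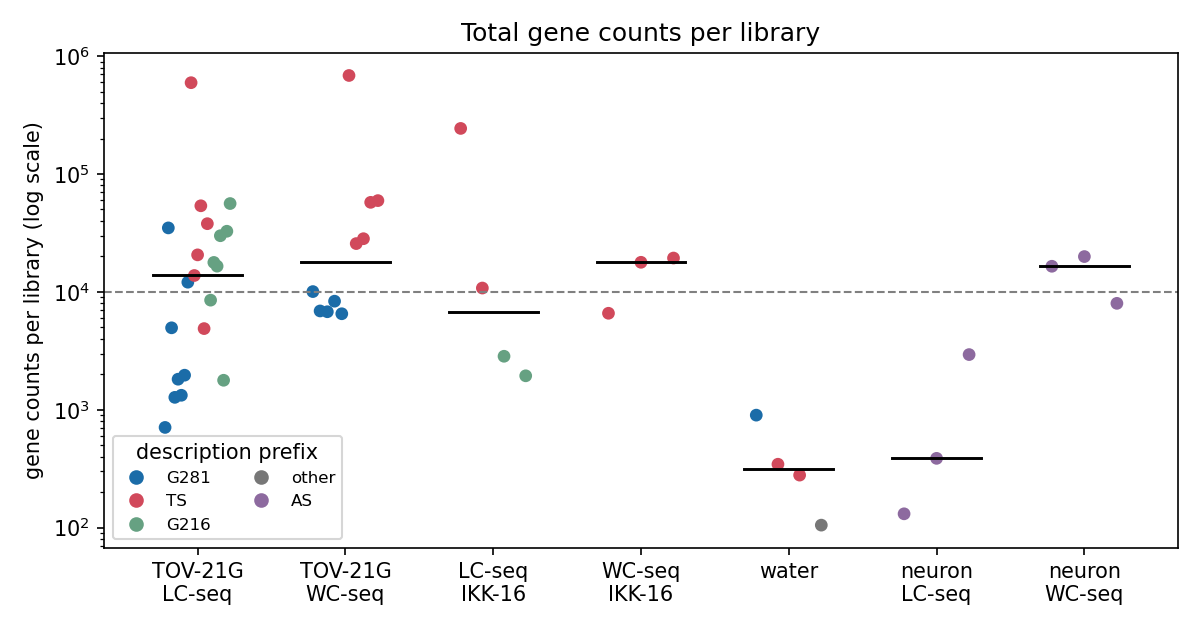
Total gene counts of each library on a log scale by group, with 1 point per library coloured by description prefix, black bars at group medians and a dashed line at 10000 counts. Water libraries lie between 105 and 900 counts, and 12 of 21 LC-seq and 6 of 10 untreated WC-seq TOV-21G libraries lie on or above the line.

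In the 1629 summed water counts, mitochondrially encoded mRNA took 0.614% (95% interval 0.295 to 1.13), against 16.6% of the summed counts in LC-seq and 6.32% in WC-seq. Ribosomal protein genes had 0 water counts, which allows a share of up to 0.184%, against 0.816% and 1.38%. Nuclear-retained RNAs also had 0, against 0.418% and 1.04%, and NF-κB targets 0, against 0.342% and 0.280%. The cells TS6 and TS9 carried 2888 of the 3246 and 2220 of the 2505 target counts, and the median target share per LC-seq library, 0.0968%, lay under the limit in water. Genes of the GENCODE type snRNA, pseudogene copies included, had 18 water counts, or 1.10% (0.656 to 1.74). Of these, 17 lay in the G281 water library, where they took 1.89% (1.10 to 3.01), and 15 of the 17 lay on RNU4-82P. HBB, the β-globin gene (ENSG00000244734, chromosome 11), had 582 of the 900 counts of that library, or 64.7% (61.4 to 67.8). HBB also had counts in all 13 cell libraries of the G281 prefix and in none of the 28 libraries outside it. Water had a median of 10.5 genes with at least 5 counts (6 to 17), against 297 in LC-seq and 322 in WC-seq. Within G281 the 8 LC-seq libraries had a median of 35.5 (13 to 372), so the lowest lay inside the range of water. The WC-seq libraries of G281 had 134 (118 to 144), and its water library 7.

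In TOV-21G the pooled LC-seq profile was richer in mitochondrially encoded mRNA and poorer in the genes of the nuclear-retained list. Of 13 mitochondrially encoded genes, which code for respiratory chain subunits, 12 had a higher mean level in LC-seq, with a list median of 0.67 on the log2 scale (9 against 4 cells). All 4 measured members of the nuclear-retained list, MALAT1, NEAT1, KCNQ1OT1 and GAS5, were lower, with a list median of -2.69. The list was fixed beforehand, and where these RNAs lay in the cell was not measured. GAS5 is a snoRNA host, so the list median is not a measure of nuclear RNA alone. MALAT1 (ENSG00000251562, chromosome 11, 65497688 to 65506516), a nuclear speckle RNA, differed by -2.74, and NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540), the scaffold of paraspeckles, by -2.80. These were the only lists of the 17 with measured members outside the random range, at percentiles 99.8 and 0.37. Of these 2 differences the nuclear-retained one exceeded the spread between cells, which was 1.45 for that list and 1.09 for the mitochondrial list.

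Among mitochondrially encoded genes the largest difference was that of MT-CO2, a cytochrome c oxidase subunit, at 1.52, followed by MT-CO1 at 1.09 and MT-ND1 of complex I at 1.04. MT-ND6 was the exception at -0.33. As a share of counts per library, mitochondrially encoded mRNA had a median of 15.4% in LC-seq (1.36 to 39.9) and 7.37% in WC-seq (2.78 to 16.3). The direction depended on the prefix: in TS libraries the medians were 15.2% and 6.65%, and in G281 libraries 5.01% and 8.10%. The G216 prefix, which holds no WC-seq library, had an LC-seq median of 30.7%. Mitochondrial rRNA had medians of 16.2% and 6.36% in all libraries, but of 3.28% in LC-seq and 5.27% in WC-seq within TS, opposite to the mRNA, and of 14.3% and 12.99% within G281. The list median was 0.53 within TS and -0.31 within G281, where 2 LC-seq cells faced 1 WC-seq cell. Nuclear-encoded respiratory chain genes did not share the direction, with 1 of 4 higher and a median of -0.66.

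Nuclear-retained RNA had a median share of 0.204% per library in LC-seq and 0.845% in WC-seq. Its median was lower in LC-seq in both prefixes, at 0.334% against 0.815% in G281 and 0.0396% against 0.943% in TS. MALAT1 had at least 1 count in 11 of 17 LC-seq and in 8 of 8 WC-seq cells, and NEAT1 in 12 and 8. Within TS, MALAT1 had 2696 CPM of summed counts in LC-seq (95% interval 2578 to 2818) and 5896 in WC-seq (5734 to 6061). The cells TS6 and TS9 held 595009 of the 725889 and 684968 of the 855847 counts behind these sums, and 2 of 5 TS LC-seq cells had a MALAT1 count. Without TS6 the LC-seq level was 2605 CPM and without TS9 the WC-seq level 6390. Within G281 MALAT1 had 4830 CPM (4285 to 5424) and 5416 (4707 to 6202), so the difference of the TS cells was not seen there. Without the cell G281_4, which held 202 of 285 LC-seq counts, it had 3440 (2740 to 4265) in LC-seq. Without the cell G281_14 it had 4760 (4014 to 5604) in WC-seq, so these intervals overlapped. NEAT1 was lower in LC-seq within G281, at 525 CPM (357 to 746) against 1529 (1164 to 1972), as was KCNQ1OT1, at 33.9 (4.10 to 122) against 441 (257 to 705). GAS5 was higher there, at 288 (168 to 461) against 130 (42.1 to 302), with 15 of its 17 LC-seq counts in G281_4 and 82.9 CPM (10.0 to 299) without that cell. In WC-seq GAS5 had 94.3 CPM (19.5 to 276) without the cell G281_13. In the list comparison GAS5, a snoRNA host, differed by -2.64 and KCNQ1OT1, an antisense RNA of an imprinted locus, by -0.46. The share also moved between libraries of 1 stem: in 8 of 8 pairs the library with the higher share of ribosomal RNA pseudogenes had the higher nuclear-retained share, as in TS7 (1.79% against 0.0363%) and TS10 (3.08% against 0.471%). These pseudogenes took a median of 2.75% of counts in LC-seq and 7.03% in WC-seq, and 0.169% and 5.02% within TS. Genes of the type snRNA, another nuclear class, took a median of 0.356% of counts in LC-seq and 1.27% in WC-seq. The difference in the list median shrank to -0.98 as a ratio of mean CPM and to -1.06 as a ratio of summed counts.

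**Figure D2:**
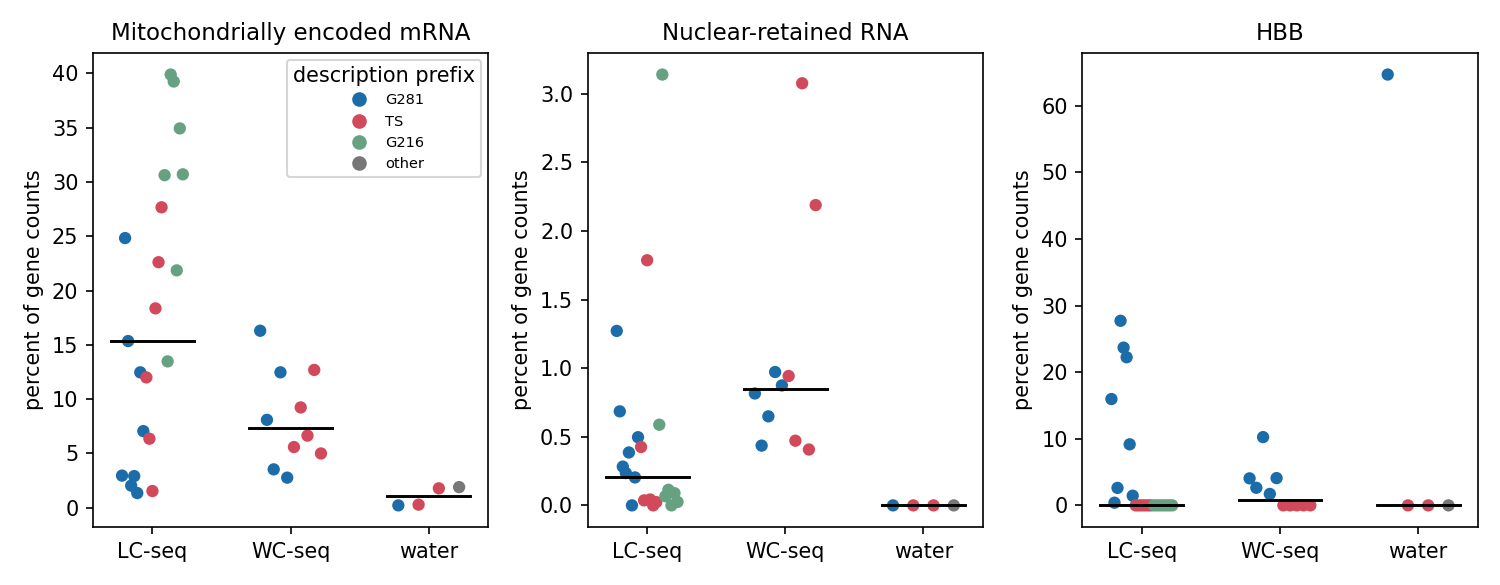
Percent of each library's gene counts on mitochondrially encoded mRNA, on nuclear-retained RNA and on HBB in untreated LC-seq, WC-seq and water libraries, with 1 point per library coloured by prefix and black bars at medians. The LC-seq median is above that of WC-seq for mitochondrial mRNA (15.4 and 7.37) and below it for nuclear-retained RNA (0.204 and 0.845), and HBB appears in G281 libraries only, water included.

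The remaining lists lay inside the random range. Membrane transporters and channels were lower for 7 of 8 genes, with a median of -1.43, beyond the spread of 1.09, at percentile 3.66, among them the amino acid transporter SLC7A5 at -1.67. Glycolysis genes were lower for 12 of 14, with a median of -1.02 at percentile 7.56; PGK1 differed by -3.45, ENO2 by -2.94 and GAPDH by -0.68. Cytosolic ribosomal proteins had 11 of 38 genes higher and a median of -0.47. Cytoskeletal genes had 6 of 20 higher and a median of -0.47, with actin ACTB at -0.63, filamin FLNA at -2.08 and the keratin KRT8 at 1.26. Ovarian clear cell carcinoma markers had 3 of 13 higher and a median of -0.57; the lineage factor PAX8 had a mean of 330 CPM in LC-seq and 409 in WC-seq. NF-κB targets had 3 of 12 higher (median -0.59), apoptosis genes 0 of 6 (-0.51) and G2/M genes 3 of 9 (-0.86).

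G1/S genes had 4 of 6 higher in LC-seq, with a median of 0.28 and the replication clamp PCNA at 1.30. Endoplasmic reticulum folding genes had 4 of 7 higher and a median of 0.01, and immediate early and stress genes 4 of 8 and a median of -0.02. NF-κB pathway components had 1 of 2 higher, with the kinase gene MAP3K14 at 1.34. Of the marker lists for foreign RNA, none of the keratinocyte genes was measured, blood had HBB and SRGN (median -0.95), and fibroblasts had COL1A1. Its mean log2(CPM + 10) was lower in LC-seq, at 4.60 against 5.60, while its mean CPM was higher, at 84.3 against 64.0. The ribosomal protein list had medians of 2.77 within G281 and -1.54 within TS, and the cytoskeletal list 3.81 and -1.72. Over all measured genes the median difference was -0.27, with 931 genes above 0 and 1346 below.

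**Figure D3:**
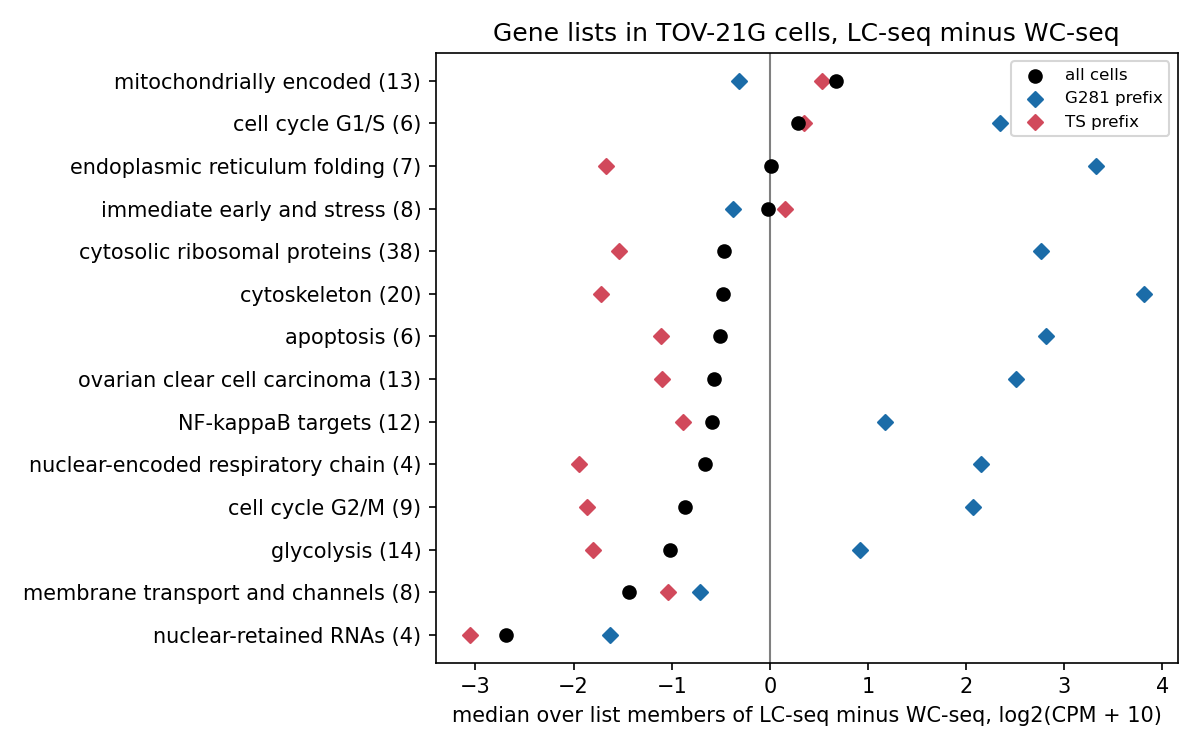
Median over the measured members of each gene list of the LC-seq minus WC-seq difference in mean log2(CPM + 10), for all cells (black), G281 cells (blue) and TS cells (red), with the number of measured members in parentheses. The nuclear-retained list is below 0 in every set of cells, at -2.69, -1.63 and -3.06, while most lists lie above 0 in G281, where 1 WC-seq cell is compared, and below 0 in TS.

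Among single genes, NPAS2 (ENSG00000170485, chromosome 2), a clock transcription factor, was the highest of those named in LC-seq. Its mean log2(CPM + 10) was 7.46 ± 3.32 (SD, n = 9 cells) in LC-seq and 3.78 ± 0.93 (n = 4) in WC-seq, a difference of 3.67. Next came the splicing factor subunit SF3B3 at 2.67, the clathrin adaptor AP2B1 at 2.56 and the initiation factor subunit EIF2S3 at 2.33. LAMA1, a laminin, differed by 2.00, the Hippo pathway coactivator WWTR1 by 1.92, CUX1 by 1.83, the calcium release channel RYR3 by 1.79, PHF12 by 1.70 and the p53 ligase MDM2 by 1.70. On the other side the ubiquitin ligase UBE3C (ENSG00000009335, chromosome 7) was at 4.05 ± 1.13 in LC-seq and 9.18 ± 3.60 in WC-seq, a difference of -5.13. The hormone gene STC1 differed by -4.00, the histone gene HIST1H4C by -3.75 and the protease inhibitor SERPINE2 by -3.53. SRPRB, PGK1, the release factor GSPT1 and DDAH1 differed by -3.48, -3.45, -3.44 and -3.42. ARL10 had 0 counts in LC-seq. It was at least 18.4-fold lower with 3 counts over the group as the limit, which covers counting error only. This bound was 6.53-fold without the LC-seq cell TS6 and 37.3-fold without the WC-seq cell TS9. Of the 20 genes taken by the naming rule, not all of which are given here, 15 differed by more than the spread between cells, which their choice by size favours, and LAMA1, CUX1, RYR3, PHF12 and MDM2 did not. The direction turned in summed counts for AP2B1 (-0.32) and STC1 (0.47), and without a library minimum for LAMA1, CUX1, RYR3 and MDM2. At a minimum of 100000 counts, with 1 cell per method, it turned for AP2B1, EIF2S3, LAMA1, PHF12, STC1 and SERPINE2. The naming rule was met by 39 genes higher and 234 lower. Across genes, the G281 and TS differences had a Spearman correlation of -0.04, and 782 of the 2277 genes had the same sign in both. The other genes were not all opposite. A difference of exactly 0 in 1 prefix, as for genes without a count in its cells, was not scored as the same sign.

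Individual TOV-21G cells resembled each other weakly. Across 2277 measured genes, which are not independent replicates, the median Spearman correlation was 0.10 between LC-seq cells, 0.22 between WC-seq cells and 0.16 between a cell of each method. Libraries of the same stem had a median of 0.21 over 5 pairs. The LC-seq pairs had 0.061, 0.248 and 0.365, beside 0.10 between different LC-seq cells. The WC-seq pairs had 0.182 and 0.208, no higher than the 0.22 between different WC-seq cells. Group means of both methods correlated at 0.35 across genes. After thinning to 5000 counts, 13 LC-seq libraries had a median of 81.8 genes with at least 5 counts and 10 WC-seq libraries 88.9. With at least 1 count the medians were 906 and 1384 genes, and 1172 and 2006 unthinned. Within TS, at 5000 counts, they were 1092 and 1002. At the planned depth of 100000 a single library of each method remained, with 1167 and 3840 genes.

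IKK-16 blocks the kinase that releases NF-κB, so its targets were the question in the treated cells. In LC-seq they took 139 of 259095 counts in the treated libraries, or 0.0536% (95% interval 0.0451 to 0.0633). In untreated libraries of the TS and G216 prefixes they took 3174 of 889250 counts, or 0.357% (0.345 to 0.370). CXCL2, a neutrophil chemokine (ENSG00000081041, chromosome 4), had 0 counts in treated and 1585 in untreated libraries, and its relative CXCL1 had 0 and 405. A count of 0 allows 11.6 CPM in the treated libraries, of whose 259095 counts 243533 lay in the cell TS11. BCL2L1, which encodes an apoptosis inhibitor, had 11 and 480 counts. The untreated cell TS6 carried 1569, 357 and 477 of the CXCL2, CXCL1 and BCL2L1 counts. Without TS6 the untreated levels were 54.4 CPM for CXCL2, 163 CPM for CXCL1 and 10.2 CPM for BCL2L1, the last below the 42.5 CPM of the treated libraries. NFKB2 had 70 treated and 42 untreated counts, and the protease gene MMP9 55 and 2. All 70 and all 55 lay in the treated cell TS11, and without it both genes had 0 treated counts, which allows 193 CPM. That limit also lies above the untreated CXCL2 and CXCL1 levels without TS6. The lower level of these chemokines in treated libraries thus rests on TS11 and TS6. The target genes TNF and LTB had no count in any library; they lie in the MHC region of chromosome 6, where 17 of 179 protein-coding genes had a count. Without TS6 the difference in share was -0.0436 instead of -0.303 percentage points. The median share per library was 0.0259% in treated and 0.0660% in untreated libraries. Both treated G216 libraries, from the cell G216_5, had 0 target counts. They held 1941 and 2843 counts in all, too few for a 0 to say much.

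The wider treated LC-seq profile rested on 2 treated and 4 untreated TS cells and 390 measured genes, with no NF-κB target among them. The actin-binding scaffold IQGAP1 (ENSG00000140575, chromosome 15) was higher by 6.59, at 11.20 ± 1.69 (SD, n = 2) against 4.61 ± 2.42 (n = 4). BCAS3 was higher by 6.25, the TATA-binding protein gene TBP by 5.56, LRRK1 by 4.96 and the RNA-binding QKI by 4.02. HGSNAT, the vesicle SNARE VAMP2, SUPT5H, the kinase JAK3 and the cohesin subunit SMC1A were higher by 3.96, 3.84, 3.77, 3.61 and 3.61. HGSNAT, with 369 treated and 1397 untreated counts, turned to -0.41 in summed counts and to -0.67 at a minimum of 100000 counts. Of the 10 genes named lower, 9 had 0 counts in the treated cells: the mRNA decay factor ZFP36L1, the hypoxia factor EPAS1, KDM5C, PTP4A2, enolase ENO1, elongation factor EEF2, SRRM2, FKBP9 and PAX8. In summed counts they were lower by at least 49.3-fold (PAX8) to at least 390-fold (SRRM2), bounds that cover counting error only. These bounds rest on TS6, which held 595009 untreated counts, and on the treated cell TS11. Without TS6 they ran from 25.6-fold (KDM5C) to 205-fold (ENO1), and without TS11 from 2.09-fold (PAX8) to 16.5-fold (SRRM2). From mean CPM over the untreated cells they ran from 45.5-fold (FKBP9) to 176-fold (ENO1), with SRRM2 at 149-fold. MT-ND4L differed by -5.90, with 10 treated and 1435 untreated counts. MT-ND4, whose annotated span overlaps the end of MT-ND4L, differed by 0.0053, with 15904 and 20381 counts. The low MT-ND4L level was thus not shared by the gene adjoining it, and the cause was not tested. In TS7, whose libraries were taken as 1 cell, 103 genes had at least 5 counts in both libraries, of 499 and 805. A low count or a 0 can therefore arise without a difference between groups, which the bounds do not cover.

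By list in LC-seq, ribosomal protein genes were lower for 9 of 9, with a median of -3.78 (-3.48 with the 7 members at 0 set to the limit), and glycolysis genes for 6 of 6, with a median of -3.72 (-3.47 with 4 at the limit). Mitochondrially encoded genes split 6 and 6, from MT-ND2 at 1.09 to MT-CO2 at -4.38 and MT-ND4L. Cytoskeletal genes were lower for 8 of 9 (median -2.43), with TPM1 higher by 1.33. Both nuclear-retained RNAs were lower, MALAT1 at -0.30 and NEAT1 at -1.70, as were P4HB of endoplasmic reticulum folding and MKI67 of G2/M. MCM4 of G1/S was higher by 0.35, apoptosis genes had 1 of 2 higher, and clear cell markers 2 of 4. The other 8 lists had no measured member. No list lay outside the random range, and the median over all measured genes was -2.25 with 109 of 390 higher, or -1.90 with the 161 genes at 0 set to the limit. The filter on counts asked for 3 cells, which the 4 untreated cells could meet alone and the 2 treated cells could not, and 0 of the measured genes were at 0 in untreated cells, so the number of lower genes partly follows from the filter. In simulated data 59 of 195 unaltered genes were higher. The simulation kept the genes measured in the real cells and did not filter simulated counts, so that lean does not measure the filter. It also altered 195 of the 390 genes in the treated cells. Group means correlated at -0.148 across genes (Spearman), and at 0.0173 without the treated cell TS23. The G216 prefix had no treated cell over 10000 counts.

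In WC-seq the NF-κB targets took 0.235% (0.192 to 0.285) of the treated counts and 0.277% (0.266 to 0.288) of the untreated TS counts, so the intervals overlapped. CXCL1 had 8 counts in treated and 422 in untreated libraries, the chemokine CXCL5 had 0 and 579, and the cytokine IL6 0 and 68. A count of 0 allows 68.5 CPM there. The untreated cell TS9 carried 387, 574 and 47 of these counts. Without it CXCL1 was at 205 CPM, against 183 CPM in the treated libraries, CXCL5 at 29.3 CPM, under that limit, and IL6 at 123 CPM. NFKBIZ, an atypical IκB gene, had 58 and 191 counts, all 58 in 1 library of the treated cell TS13 and all 191 in TS9. Of 3 measured targets, CXCL1 differed by -2.26, the urokinase gene PLAU by -1.09 and BCL2L1 by 0.45, giving a median of -1.09 at percentile 79.0. The direction turned with the setting: without the treated cell TS13 the median was 0.44, and without TS14 -2.48. Without the untreated cell TS9 the difference in share turned from -0.0413 to 0.149 percentage points.

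Across the 512 genes measured in 2 treated and 3 untreated WC-seq cells, the nuclear import receptor IPO7 (ENSG00000205339, chromosome 11) was higher by 4.27 and the ribosomal protein gene RPS27 by 3.98. FAM173B was higher by 3.89, the RNA-binding LARP1 by 3.63, BRD3 by 3.25, the kinetochore gene CENPF by 3.07, utrophin UTRN by 2.79, the nuclear envelope gene SYNE1 by 2.65, STAG2 by 2.55 and RPL36 by 2.11. All 10 genes named lower had 0 treated counts: HCFC1, UBE3C, the metallothionein MT2A, HNRNPA2B1, PLS3, the chromatin protein gene HMGA1, the transferrin receptor TFRC, TBL1X, RPL19 and the chaperone HSP90AB1. They were lower by at least 9.60-fold (RPL19) to at least 20.4-fold (TBL1X), with 80.7 CPM as the limit over the treated libraries of at least 10000 counts. These bounds too cover counting error only. The lowest of these bounds was 2.87-fold without the untreated cell TS12 (TBL1X), 3.08-fold without TS10 (UBE3C) and 3.99-fold without TS9 (HSP90AB1). It was 4.60-fold without the treated cell TS14 and 5.00-fold without TS13 (both RPL19). The treated cells, with 37186 counts in all, were the shallowest TOV-21G group over the minimum. A median of 1022 genes had a count in treated libraries and 1991 in untreated TS libraries. Mitochondrially encoded mRNA took 18.5% of the treated and 6.17% of the untreated counts, with 32.2% in TS14 and 9.61% and 6.74% in the libraries of TS13. In LC-seq it took 26.3% of the treated and 16.5% of the untreated counts, while the medians per library were 4.24% and 22.6%.

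By list in WC-seq, glycolysis genes were lower for 9 of 9 (median -3.04, or -1.22 with 4 members at 0 set to the limit) and cytoskeletal genes for 13 of 14 (-2.45, or -2.27 with 2 at the limit). Ribosomal proteins were lower for 15 of 18 (-2.27, or -1.94 with 6 at the limit), clear cell markers for 9 of 10 (-2.56, or -1.51 with 2 at the limit) and nuclear-retained RNAs for 3 of 3 (-2.52). Mitochondrially encoded genes were higher for 7 of 12, with a median of 0.35 and MT-ND4 at 1.99. Both transport genes were higher, SLC16A3 of lactate export by 1.69 and CLIC4 by 0.15. The median over all genes was -2.53, or -1.02 with the 199 genes at 0 set to the limit, with 389 of 512 lower, and no list lay outside the random range. The filter favoured genes of the 3 untreated cells here too. In simulated data, to which the filter was again not applied, 93 of 312 unaltered genes were higher. Group means correlated at 0.122 across genes (Spearman). G2/M genes had 1 of 3 higher, endoplasmic reticulum folding genes 0 of 3, and apoptosis genes 1 of 2; ATP5F1B of the respiratory chain and SRGN were lower. The other 5 lists had no measured member.

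In the cortical neurons, WC-seq cells held more genes than LC-seq cells, and most counts in both fell on few genes. At least 1 count was found for 139 to 286 genes in WC-seq and 26 to 116 in LC-seq. The gene ENSMUSG00000098178 took 81.9, 73.2 and 15.0% of the counts in the WC-seq cells and 3.05, 32.3 and 40.3% in the LC-seq cells. ENSMUSG00000075015 had 278 of 44417 counts in WC-seq and 0 of 3456 in LC-seq, where a count of 0 allows 868 CPM. It was the single gene that met the naming rule, whose limit to protein-coding genes could not be applied in mouse. Of 635 genes with a count in any cell, 164 had one in LC-seq, 525 in WC-seq and 54 in both. Thinned to 100 counts, LC-seq cells had a median of 20.5 genes with a count (16.3 to 21.6) and WC-seq cells 10.99. The WC-seq cells in which ENSMUSG00000098178 took 81.9 and 73.2% of counts had 9.31 and 10.99 genes. The WC-seq cell in which it took 15.0% had 21.9. The thinned numbers thus follow the share of that gene and do not settle the part of depth. Over 21 measured genes, 9 were higher in LC-seq and 12 lower, and group means correlated at 0.39 (Spearman across genes).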

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

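The tests of HBB, of prefixes, of snRNA, of ribosomal RNA pseudogenes and of the WC-seq NF-κB list were chosen after the results were seen. Those of mitochondrial composition, depth and detection were set before. Single cells far from their group came from a gap rule that chance meets in about 1 in 20 groups, and 4 of the 8 quantities examined met it, all in untreated WC-seq, the only group with 4 to 10 cells.

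HBB, the β-globin gene, took 64.7% of the counts of the G281 water library, a blank outside the comparisons of cells, and had counts in all 14 G281 libraries and in none of the other 28. Expression by TOV-21G cells, the biological explanation tested, is argued against by the 582 counts in water. HBB counts differed 6.15-fold between the highest and the lowest G281 library, while the counts of all other genes differed 109-fold, so a like amount of HBB material entering each library of that batch is a candidate explanation. Reads from blood cells cannot be told apart from it by the α-globin genes HBA1 and HBA2, which had 0 counts beside 4092 of HBB, because reads of these near-identical copies may not be countable by gene. The design names no group that differs in globin.

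Nuclear-retained RNAs were lower in LC-seq than in WC-seq, with a list median of -2.69 and a spread between cells of 1.45. The tables argue against mitochondrial RNA filling the LC-seq counts as the whole cause, since the median was -2.49 with totals free of it. They also argue against a difference between prefixes as the whole cause, since the median was -3.06 within TS. Batches inside a prefix stay open, because the labels do not say what a prefix is. Ribosomal RNA pseudogenes took a median of 0.169% in LC-seq and 5.02% in WC-seq libraries within TS. Depth stays open: as a ratio of mean CPM, which low depth leaves unbiased, the median was -0.98, within 1 spread of 0. So does library preparation: in 8 of 8 pairs of libraries of 1 stem, the library richer in ribosomal RNA pseudogenes was richer in nuclear-retained RNA. Less the change that went with these pseudogenes in the 5 pairs over 10000 counts, the median was -0.44 (-0.795 to -0.0616 without single pairs), also within 1 spread of 0. It was 0.98 within TS and -0.71 within G281, which holds no pair. This assumes that both libraries of a pair hold RNA of 1 cell. A smaller yield of nuclear RNA through the pipette in the living-cell collection cannot be told apart from these. Within TS, snRNA, another nuclear class, had a median share of 0.377% in LC-seq and 1.71% in WC-seq. Within G281 the medians were 0.676% and 0.811%, below the 1.89% of the G281 water library. That water share came from few counts, 15 of them on RNU4-82P, so it says little of other snRNA genes. The snRNA gene RNU4-2 was lower in LC-seq within G281, at 1525 CPM of summed counts (1226 to 1875) against 2747 (2249 to 3322). Within TS it had 631 against 8976 CPM. Neither the G281 shares nor this 1 gene decides between these explanations.

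NF-κB target genes mostly lacked counts in IKK-16-treated cells by LC-seq, where 6 of the 28 targets seen in untreated cells had a count. Detection alone could give this: lists matched on level held 3.65 such genes on average, and 6 lies at percentile 89.4 of them. Lower target RNA under IKK-16, the effect the design names, cannot be told apart from it, because WC-seq measured 3 targets, whose median lay at percentile 79.0 of matched lists.

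The WC-seq cell TS9 had 684968 counts, with 58471 in the next cell. It also had 6710 genes with at least 5 counts, with 741 in the next. In the WC-seq cell G281_12, NF-κB targets took 1.44% of counts, with 0.324% in the next cell, and 80 of its 99 target counts lay on NFKBIA, the gene of the inhibitor IκBα. In the WC-seq cell TS12, snRNA genes took 4.07% of counts, with 1.84% in the next cell. This cell has 2 libraries, at 6.84% and 1.30%, so the gap rests on the first of them.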

How the results depend on the processing

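Without libraries marked dup, a total without HBB, thinning to 5000, 1 count at 5000 or unthinned, shares of libraries over 10000 counts, NF-κB shares of summed counts, and IKK-16 values without each untreated cell, with single targets and bounds of genes at 0, were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the titles number cells within a collection and no test was made. The mitochondrial list median stayed above 0 in 19 of 20 settings (highest 1.28) and reversed to -0.31 within G281, as did its share (-3.09 percentage points). The nuclear-retained median stayed below 0 in all 20 (-3.34 to -0.98); it moved to -0.98 as a ratio of mean CPM and -1.06 of summed counts. Leaving out 1 WC-seq cell gave 0.49 to 1.05 and -2.67 to -2.18. The ribosomal protein share, 0.0252 points higher in LC-seq, reversed to -0.562 in summed counts, -0.477 within TS and -0.218 in libraries over 10000 counts. The correlation of group means moved from 0.350 to 0.234 at a minimum of 100000 counts, 0.241 within G281 and 0.120 within TS. That between WC-seq cells moved to 0.293 as Pearson's r. In neurons it moved from 0.386 to -0.374 without a filter, which admits genes seen in 1 method only. The WC-seq to LC-seq ratio of detected genes, 3.29 at 100000 counts, was 0.846 at 50000, 1.09 at 5000 and 1.08 unthinned, or 1.53 and 1.71 at 1 count; at 100000 it compares single libraries. The LC-seq to water ratio, 28.3 over all prefixes, was 12.7 at 1 count.

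Of the 20 genes taken by the LC-seq and WC-seq naming rule, 11 never reversed. Without a library minimum LAMA1 (-0.15), CUX1 (-0.67), RYR3 (-0.28) and MDM2 (-0.32) reversed. At a minimum of 100000, which leaves 1 cell per method, AP2B1 (-2.33), EIF2S3 (-0.26), LAMA1 (-1.82), PHF12 (-3.22), STC1 (1.45) and SERPINE2 (0.11) did. In summed counts AP2B1 (-0.32) and STC1 (0.47) did. With IKK-16, HGSNAT reversed in summed counts (-0.41) and at the 100000 minimum (-0.67); the other 19 LC-seq and all 20 WC-seq named genes never did, but 9 and 10 of them have 0 treated counts and hardly can.

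The WC-seq NF-κB median, -1.09, was -2.67 at pseudocount 1, 0.00118 at 100, 0.72 as a ratio of mean CPM and 0.10 of summed counts, and -2.48 to 0.44 without a treated cell. The share difference in LC-seq, -0.303, was -0.0401 as a median over libraries, -0.0979 within G216 and -0.325 to -0.0436 without single cells. The G216 value rests on 0 target counts in the shallow libraries of the treated cell G216_5. In WC-seq, -0.0413 became 0.0740 as a median and lay between -0.178 and 0.149 without single cells. Without single cells, treated minus untreated CPM ranged from -553 to 167 for BCL2L1, -47.2 to 240 for NFKB2 and -2.25 to 219 for MMP9 in LC-seq, and from -223 to 2153 for NFKBIZ in WC-seq. Except where stated, the cause was not tested. Medians of the other lists kept their sign in 247 of 300 values for LC-seq against WC-seq, 175 of 200 and 186 of 192 with IKK-16, where members at 0 in treated cells favour it. The correlation of treated and untreated LC-seq means, -0.148, lay between -0.259 and 0.193. No value came from G216 alone (IKK-16 in LC-seq), from a 100000 minimum or without dup libraries (IKK-16 in WC-seq), or from thinned LC-seq cell pairs; mouse lists and a mouse total without mitochondrial genes were not run. Depth limits what a count of 0 shows: it allows 868 CPM in LC-seq neurons, 68.5 CPM in treated WC-seq and 11.6 CPM in treated LC-seq libraries (193 CPM without TS11).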

Other observations

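BCL2, which encodes an apoptosis inhibitor, was carried by single cells. The IKK-16-treated LC-seq cell TS11 had 17935 BCL2 counts, or 7.36% of its total (95% interval 7.26 to 7.47), and the untreated WC-seq cell TS9 had 16922, or 2.47% (2.43 to 2.51). The next highest library, the untreated LC-seq cell TS6, had 243 counts, and 9 of the 42 human libraries had any.

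Among keratinocyte genes, KRT14 had 10 counts in all of untreated LC-seq and 2 in WC-seq. The fibroblast collagen COL1A1 had 66 and 35, and the blood cell proteoglycan SRGN 125 and 289. The mean level of SRGN was 291 CPM in LC-seq and 221 CPM in WC-seq, beside 330 and 409 CPM for PAX8, a marker of clear cell carcinoma. HBB, another gene of the blood list, took a median of 12.6% of the counts of G281 LC-seq libraries. KRT8, an epithelial keratin, had counts in 5 of 17 LC-seq and 1 of 8 WC-seq cells. PAX8 had counts in 11 LC-seq and 7 WC-seq cells.

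In the MHC region of chromosome 6, 17 of 179 protein-coding genes had a count in any human library (9.50%, 95% interval 5.63 to 14.8). In the next 5 Mb 50 of 62 did, in the preceding 5 Mb 65 of 106, and over all 19817 protein-coding genes 70.3%. Among the members of the fixed lists that lie there, TNF, LTB, RPS18, TUBB, CLIC1, HSPA1A and HSPA1B had no count.

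Of 8 pairs of cell libraries with a shared stem, the one marked dup had the higher share of ribosomal RNA pseudogenes in 6. In TS12 it was 57.8% against 7.03%, and in TS13 39.2% against 3.49%; G216_4 and G216_5 were the exceptions. The water pair TS15 had 0 such counts in both libraries. No 2 libraries had identical counts among 859 pairs compared.

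In water, NALCN-AS1 led in one TS library with 93 of 345 counts, KCNK2 and CHRNA2 with 20 counts each of 279 in the other, and RTKN2 with 23 of 105 in the library outside the prefixes.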
